A study of Rattus norvegicus with 3 samples.

How the data were processed

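Rat brainstem RNA was measured on 3 Affymetrix arrays, 1 labelled sham, 1 TBI and 1 hand acupuncture, all taken 1 h after modelling. Per the labels' protocols, brainstem was frozen, total RNA was extracted with Trizol, and biotin-labelled cRNA was made from 6 µg of RNA. Per the series' design text, samples of 5 animals were mixed, which is read here as 1 pool per group. MAS5, Affymetrix's method that turns a probe set's perfect-match and mismatch probes into 1 signal, is named in the submitters' processing notes, with no version. The deposited values are log2 signals: raised to the power of 2, the mean signal with 2% trimmed at each end was 500.0 on every array, which is how MAS5 scales arrays to a common target, so the log base and the scaling were read from the values. Detection calls were not used here, so the floor below stands in for them. Because MAS5 subtracts mismatch signal, values near background are erratic: over probe sets the SD of TBI minus sham was 1.76 in the lowest decile of mean signal and 0.14 in the highest. In the lowest decile the hand acupuncture array was also higher than the TBI array by a median of 0.26.

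Probe sets were named through the platform annotation of 2016. Of 31099 probe sets 57 were controls, and of the other 31042, 20826 had 1 gene symbol, 436 had several and 9780 had none in that table and were left unnamed. These gave 14217 genes, of which 14167 were found by identifier in a RefSeq table of the assembly GRCr8, and 0 symbols needed updating. No genome was used here, so no coordinates are given. A gene was represented by its brightest probe set over the 3 arrays among those with exactly 1 symbol. Genes were described if their mean log2 signal was at or above the median of non-control probe sets, 7.44, which left 9241. Of these, 2073 had at least 2 probe sets above the floor.

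The comparisons, the floor, the 35 lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where a choice is stated to have been made later. Each group is 1 array of pooled RNA, so no test was run and no p-value is given. For each comparison the log2 difference of the 2 arrays was taken as deposited, and genes at least 2-fold apart were counted. For 35 gene lists of cell types, regions and responses, the median log2 difference of the members above the floor was set beside its percentile among 10000 random lists of the same size matched on mean signal in 20 bins. A list is said to stand apart outside the 2.5th to 97.5th percentile, and members at least 1.5-fold apart were counted. Lists with fewer than 4 members above the floor, 3 of the 35, have values only. Of 32 lists, 11 stood apart for TBI minus sham, 9 for hand acupuncture minus TBI and 10 for hand acupuncture minus sham, where about 1 in 20 would by chance. Random lists hold unrelated genes, whereas genes of one cell type vary together, so real lists leave the central range more often than 1 in 20 without any effect of treatment. The percentile describes these arrays and is no test of the conditions.

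Named genes followed a fixed rule. It took the 10 highest and 10 lowest for the 2 comparisons with TBI, the 5 highest and 5 lowest for hand acupuncture minus sham, up to 4 members with the largest difference for lists that stood apart and for the stress, immune and cell type lists, and the 5 genes with the largest gap for each array apart from the others. Other probe sets of a named gene were checked for direction. Other members were named where they help to describe a list, after their values were seen. Comparisons that share an array are related by construction, so correlations of differences were set beside those from 100 shuffles of each gene's 3 values among the arrays. The leading lists (cerebellum, neuropeptides and glucocorticoid-responsive genes) were chosen after all lists had been looked at in all 3 comparisons.

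RNA and labelling controls were read on each array. The ratio of 3' to 5' probe sets was 5.58 for beta-actin on the sham array, 6.37 on the TBI array and 6.69 on the hand acupuncture array, and 1.25, 1.20 and 1.28 for Gapdh. TBI minus sham was 0.18 in the median of hybridisation controls and 0.40 in that of the controls added before labelling. The latter had median log2 signals of 6.99, 7.39 and 6.55 on the sham, TBI and hand acupuncture arrays, all below the floor of 7.44.

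Alternatives were quantile normalization, centring on the median, a higher floor on mean log2 signal (9.25), no floor, an offset of 50 before the log, the mean of all probe sets of a gene, probe sets in place of genes, agreement of all probe sets, and thresholds of 1.5-fold and 3-fold. For lists, each member was left out in turn. The 1.5-fold threshold for genes with 1 array apart was added after seeing the data. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. They were first tested on simulated data for the 9241 genes: with 200 genes changed 2.5-fold, 91.5% were recovered for TBI minus sham, 96.5% for hand acupuncture minus TBI and 91.0% for hand acupuncture minus sham. Of simulated unchanged lists of 17 genes 5.0%, 4.0% and 5.0% stood apart in the same order, and all lists shifted by 0.3 did. The simulated genes varied independently and the lists were drawn at random. The simulation thus checks the scripts and not how often real lists, whose genes vary together, stand apart.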

Results

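The series holds 3 expression arrays of rat brainstem, 1 from each of 3 groups, taken 1 h after modelling. The groups are sham, TBI (traumatic brain injury) and hand acupuncture. The treatment label of the last reads Hand Acu, which by itself does not say how or where needles were placed. The labels give 5 rats, whose brainstem tissue was mixed, and 6 µg of total RNA for labelling. The series is about how acupuncture regulates genes of the brainstem, so TBI was set against sham, hand acupuncture against TBI, and hand acupuncture against sham. The labels do not say whether the rats given acupuncture were also injured. Each array measured 31099 probe sets, with a median signal of 174.7 on the sham array, 174.1 on the TBI array and 174.2 on the hand acupuncture array. Of 14217 named genes, 9241 lay above the floor on mean signal and are described unless stated otherwise. There was no replicate, so no difference below has an error of its own, no test was run, and differences are between 3 pools of RNA. The number of arrays limits the precision. The ratio of 3' to 5' beta-actin signal, a sign of RNA integrity, was 5.58 on the sham array, 6.37 on the TBI array and 6.69 on the hand acupuncture array. Over all genes above the floor, the SD of the log2 differences was 0.20 for TBI minus sham, 0.19 for hand acupuncture minus TBI and 0.21 for hand acupuncture minus sham.

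TBI against sham asks what differs in the brainstem 1 h after injury. Genes that mark the cerebellum were lower on the TBI array, and genes of neuropeptides and opioid receptors were higher. A list of genes that respond to glucocorticoids, the steroid hormones of the stress response, was higher in median, as were markers of microglia, the immune cells of the brain. A second set of glucocorticoid-responsive genes did not stand apart (median 0.06, percentile 90.47). Immediate early genes, which are switched on within minutes of cell stimulation, had a median log2 difference of 0.02 and heat shock genes of 0.04. Of the single genes, 6 were at least 2-fold higher and 3 at least 2-fold lower, and at 1.5-fold the numbers were 80 and 63.

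Of 17 cerebellum markers above the floor, 16 were lower on the TBI array, 5 of them at least 1.5-fold, and the median log2 difference was −0.41 (1.33-fold lower, percentile 0.0 among random gene lists of like signal). Slc1a6, a glutamate transporter of Purkinje cells, differed by −0.76 and Fat2, a protocadherin of granule cells, by −0.76. En2, a homeobox gene of the midbrain and cerebellum, differed by −0.70 and Gabra6, a GABA-A receptor subunit of granule cells, by −0.62. In the other direction, 21 of 23 neuropeptide and opioid receptor genes were higher, none of them by 1.5-fold, with a median of 0.36 (percentile 100 among random lists) that was 0.23 with a higher floor of 9.25 in mean log2 signal and 0.24 with no floor. Oxt, the gene of oxytocin, was 0.58 higher and Pnoc, the precursor of nociceptin, 0.55 higher. Grp, the gene of gastrin-releasing peptide, was 0.54 higher and Calca, the gene of calcitonin and CGRP, 0.53 higher. The 4 cholinergic and motor neuron genes above the floor were all higher, with a median of 0.21, among them Chat, which makes acetylcholine, at 0.25. Monoaminergic neuron genes had a median of 0.12, with 10 of 14 higher. Gch1, an enzyme that makes the cofactor of monoamine synthesis, was 0.85 higher and Slc6a4, the serotonin transporter, 0.48 higher, while Htr2a differed by −0.48. Forebrain markers had a median of 0.14, with 11 of 15 higher, among them Adora2a at 0.75 and Ppp1r1b, the gene of DARPP-32, at 0.60, while Neurod2 was lower at −0.56. The medians of the cholinergic and monoaminergic lists lay within the central 95% of random lists with no floor, and so did the monoaminergic median with the higher floor, which left the cholinergic list too few members for a percentile. The forebrain median was 0.23 with the higher floor. Of the further probe sets of a list's members above the floor, 2 of 2 went the way of the probe set used for cerebellum markers, 1 of 2 for neuropeptide, 3 of 3 for monoaminergic and 2 of 5 for forebrain genes.

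Glucocorticoid-responsive genes had a median log2 difference of 0.18, with 14 of 19 higher and none by 1.5-fold (percentile 100); 3 of 4 further probe sets went the same way. Pdk4, a kinase that restrains glucose oxidation, was 0.57 higher, Cdkn1a, the cell cycle inhibitor p21, 0.54 higher, Cebpd, a transcription factor, 0.48 higher and Mt2A, a metallothionein, 0.44 higher. Microglia and macrophage markers had a median of 0.18, with 10 of 14 higher (percentile 99.84), including the purinergic receptor gene P2ry12 at 0.51 (its other probe set went the opposite way), Mrc1 at 0.31 and the complement gene C1qc at 0.30. All 7 pericyte and smooth muscle markers were lower, with a median of −0.24, and Tagln, a smooth muscle actin-binding protein, was the lowest at −0.64. Choroid plexus and ependymal markers had a median of 0.13, with the ciliated cell genes Dynlrb2 at 0.58 and Foxj1 at 0.49, and nuclear genes of oxidative phosphorylation had a median of 0.07. The medians of the pericyte, choroid plexus and oxidative phosphorylation lists lay within the central 95% of random lists with no floor. The higher floor left the pericyte list too few members for a percentile and put the other 2 lists within that range, as did quantile normalization, with medians of 0.06 for choroid plexus and 0.02 for oxidative phosphorylation genes; the choroid plexus median was also within it with the mean of all probe sets of a gene, at 0.05. Of further probe sets, 0 of 1 for pericyte markers and 1 of 3 for oxidative phosphorylation genes went the same way. The 3 blood cell genes above the floor were also higher, with Hbb, a haemoglobin chain, at 0.33, Alas2, the haem enzyme of red cells, at 0.32 and Pf4, a platelet chemokine, at 0.51.

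Within the immediate early list, 14 of 27 genes were higher and 13 lower, so members went both ways: Fosb was 0.86 higher, Fos and Nr4a3 each 0.48 higher and Egr2 0.45 higher, while Dusp5 differed by −0.56 and Nr4a1 by −0.41. Of the 12 further probe sets of these genes above the floor, 5 went the way of the probe set used. Hspb1, a small heat shock protein, was 0.66 higher and Hspa4 differed by −0.37, with 11 of 18 heat shock and chaperone genes higher. Of inflammatory mediators, 6 were above the floor and 5 of those were higher, with a median of 0.17 (percentile 97.40); Tnfaip3, an inhibitor of NF-kappaB signalling, was 0.30 higher and Ptgs2, the inducible cyclooxygenase, 0.24 higher. Astrocyte markers had a median of 0.06, with Gfap at 0.30, and endothelial markers of −0.11, with Cldn5, a tight junction gene, at −0.44. Neuron markers had a median of 0.05, myelin and oligodendrocyte markers of 0.08, oligodendrocyte precursor markers of −0.00 and meningeal and fibroblast markers of 0.10. The median was 0.08 for antioxidant genes, 0.11 for interferon and antigen presentation genes, 0.03 for hypoxia and glycolysis genes, 0.05 for apoptosis regulators and 0.02 for genes of the unfolded protein response. It was 0.02 for inhibitory transmission genes, 0.01 for glutamatergic transmission genes, 0.02 for neurotrophic factors and receptors, −0.05 for circadian clock genes and 0.08 for midbrain, thalamus and hypothalamus markers. Housekeeping genes had a median of 0.02, ribosomal protein genes of 0.06 and the 2 male-specific genes above the floor of 0.18. Pituitary and skeletal muscle markers stood apart in each comparison, at −0.19, 0.20 and 0.48 in the order named above, but their median is that of 5 genes around Myh1, whose 5 probe sets did not go one way, and for TBI minus sham it turned to 0.27 with the mean of all probe sets of a gene. Its members went both ways. The pituitary genes Cga and Tshb were 0.72 and 0.36 higher for TBI minus sham, and 0.49 and 0.68 higher for hand acupuncture minus sham. Pvalb and Acta1 each differed by −0.24 for TBI minus sham, and by −0.33 and −0.04 for hand acupuncture minus sham.

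Ranked by size, the genes highest on the TBI array over the sham array were Palmd, which encodes palmdelphin (log2 signal 7.89 on the sham array and 9.30 on the TBI array, 2.65-fold), and Hoxa5, a homeobox gene of the caudal hindbrain and spinal cord (2.33-fold). Ttll11, a tubulin glutamylase, Harbi1, Aven, an inhibitor of apoptosis, and Ranbp1, a partner of the Ran GTPase, were 2.10-fold, 2.08-fold, 2.06-fold and 2.03-fold higher. Iffo1, Tmem255a, Pde6g and Tmem252 followed, from 1.98-fold to 1.92-fold. The lowest on the TBI array was Col4a2, a collagen IV chain of basement membranes (8.19 against 6.80, 2.61-fold lower). Per3, a gene of the circadian clock, was 2.25-fold lower and Nhsl2 2.09-fold lower. Tnfrsf11b, which encodes osteoprotegerin, and Exph5 were 1.98-fold lower, and Plaa, Herc1, Rnf39, Klhl42 and Brcc3-ps7 lay between 1.90-fold and 1.76-fold lower. Each of these had 1 probe set above the floor except Plaa, whose other probe set went the opposite way. None of the 9 genes past 2-fold was above the higher floor, and without any floor 1034 genes passed 2-fold. Across the 2073 genes with several probe sets above the floor, the differences of the first pair correlated at r = 0.20 over genes, which are not independent replicates, and 57.4% had the same direction; for hand acupuncture minus TBI these were 0.11 and 54.0%, and for hand acupuncture minus sham 0.16 and 55.5%.

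**Figure D1:**
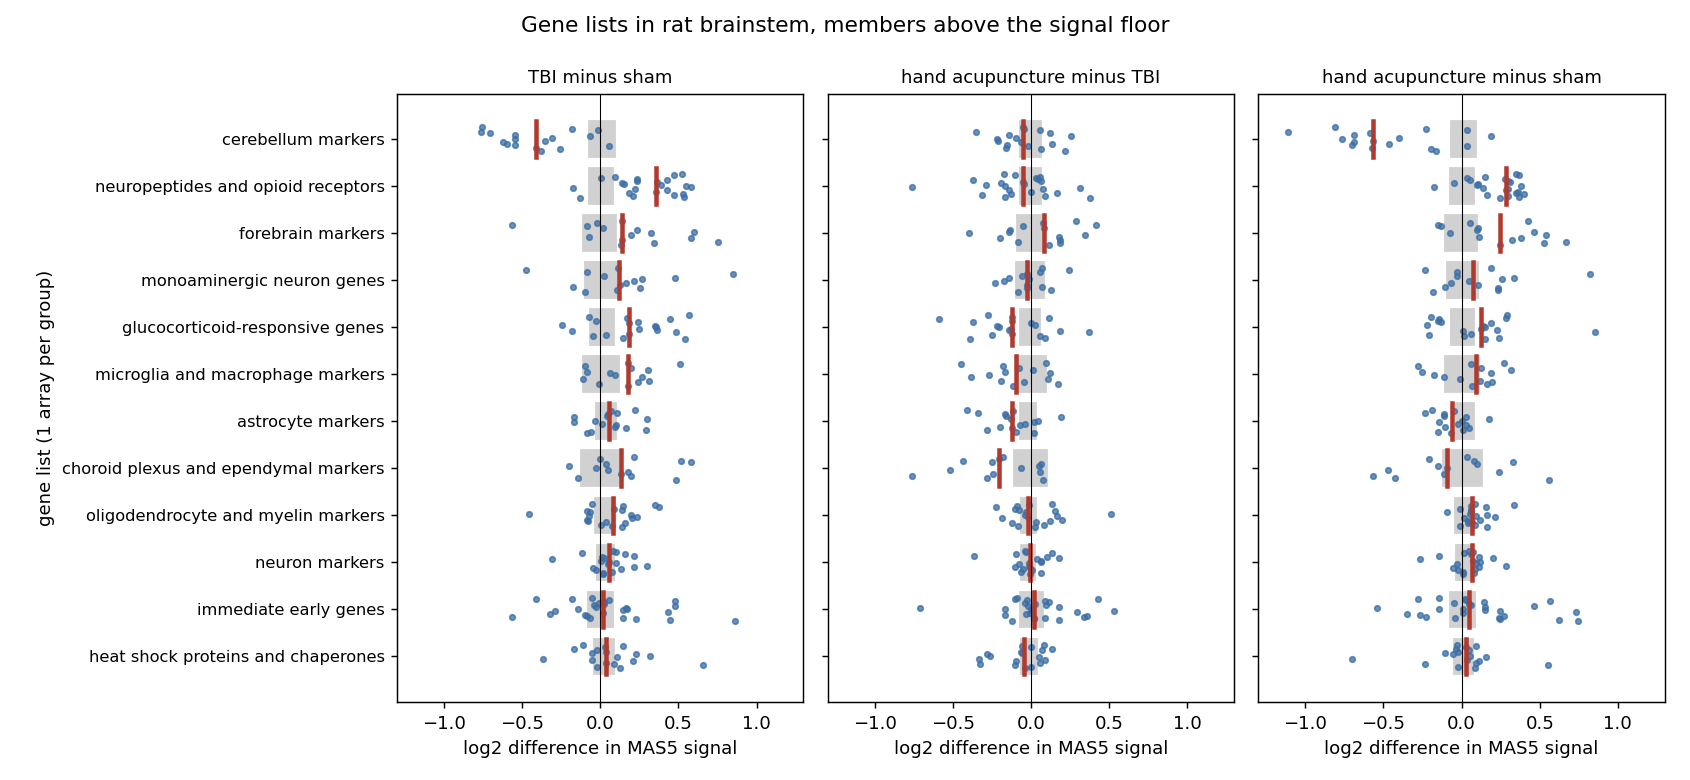
Log2 difference in signal (x axis) of the members of 12 gene lists above the floor (y axis), with 1 array per group; blue points are genes, red bars the list medians and grey boxes the central 95% of medians of random lists of like signal. Against sham, in both outer panels, most cerebellum markers lie to the left of 0 (16 and 14 of 17), with medians of −0.41 and −0.57, and most neuropeptide genes to the right (21 of 23 in each), with medians of 0.36 and 0.29.

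Hand acupuncture against TBI asks how the brainstem after acupuncture differs from that after injury. Fewer genes were 2-fold apart here, with 3 higher and 1 lower on the hand acupuncture array, and at 1.5-fold the numbers were 57 and 55. With the mean of all probe sets of a gene the order at 2-fold turned, with 13 genes here and 12 for TBI minus sham. Astrocyte markers, choroid plexus and ependymal markers, and glucocorticoid-responsive genes were lower on the hand acupuncture array. Cerebellum markers had a median of −0.05 and neuropeptide genes of −0.05, both within the central 95% of random lists; with the mean of all probe sets of a gene the neuropeptide median was −0.13, outside it.

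Of 16 astrocyte markers, 12 were lower on the hand acupuncture array than on the TBI array, with a median log2 difference of −0.12 (percentile 0.03), which was −0.07 under quantile normalization and still outside the range of random lists; of the further probe sets of these genes, 5 of 10 went the way of the probe set used. Fgfr3 differed by −0.41, with its other probe set the opposite way, the gap junction gene Gjb6 by −0.34, Gfap, the intermediate filament of astrocytes, by −0.28, and Glul, the glutamine synthetase gene, by −0.19. Choroid plexus and ependymal markers had a median of −0.20, with 9 of 13 lower, among them Prlr, the prolactin receptor, at −0.76, Sostdc1 at −0.51 and Ttr, the transthyretin gene, at −0.24. Glucocorticoid-responsive genes had a median of −0.12, with 12 of 19 lower (percentile 0.05) and 2 of 4 further probe sets the same way; Mt2A differed by −0.59, Cdkn1a by −0.39 and Angptl4 by −0.37, while Cebpd was 0.37 higher. Inhibitory transmission genes had a median of −0.09, with Glra2, a glycine receptor subunit, at −0.51. Meningeal and fibroblast markers had a median of −0.10, with Fbln1 at −0.49, but lay within the central 95% of random lists under quantile normalization, with no floor and with the higher floor. Of 39 ribosomal protein genes, 35 were lower, by a median of −0.06, where random lists of like signal had −0.03. The ribosomal median was not outside the range of random lists with the higher floor and was −0.02, still outside it, under quantile normalization. The clock list had a median of 0.11, with Dbp 0.58 higher, Per3 0.55 higher and the repressor gene Nfil3 at −0.66, and its median was −0.03 with the mean of all probe sets and 0.05 with no floor, both within the range of random lists, and 0.18 with the higher floor. For hypoxia and glycolysis genes the median was 0.05, with Ankrd37 0.69 higher and Pfkfb4 0.63 higher, and it was −0.0006 with the higher floor and with the mean of all probe sets. With that mean Pfkfb4 turned to −0.17. Of further probe sets, 2 of 5 for inhibitory transmission, 0 of 4 for meningeal, 4 of 5 for ribosomal, 4 of 5 for clock and 2 of 4 for hypoxia and glycolysis genes went the same way.

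Lists within the central 95% of random lists included the immediate early genes, with a median of 0.02 and 16 of 27 higher; Atf3 was 0.53 higher, Nr4a1 0.43 higher and Gadd45b differed by −0.71. Heat shock genes had a median of −0.05, with Hspa4 and Cryab each at −0.33, and inflammatory mediators of −0.13, with Tnfaip3 at −0.27. Microglia and macrophage markers had a median of −0.09, with P2ry12 at −0.45, again against its other probe set, and C1qb at −0.38. Endothelial markers had a median of 0.03, with Eng at −0.55 and Emcn 0.51 higher, and pericyte markers of −0.06. Neuron and myelin markers had medians of −0.01 and −0.02. Hbb differed by −0.40 and Alas2 by −0.26, so that Hbb was 13.46, 13.79 and 13.39 in log2 signal on the sham, TBI and hand acupuncture arrays.

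By size, Col4a2 came first among genes higher on the hand acupuncture array (2.68-fold over TBI, and 1.03-fold over sham). Lrrc4, which encodes a netrin-G ligand of synapses, was 2.29-fold higher and Tchp 2.02-fold higher. Cenpx, a centromere protein gene, the receptor phosphatase gene Ptpru, Slc4a11 and Synm, an intermediate filament gene, were 1.94-fold to 1.86-fold higher. Tatdn1, Ric3, a chaperone of nicotinic receptors, and the sodium-proton exchanger gene Slc9a2 were 1.81-fold to 1.80-fold higher. Fbxo41 was 2.35-fold lower, followed by the cell polarity gene Llgl1 (1.94-fold) and by Ccdc77, whose 2 probe sets were both lower (1.91-fold). The synaptic genes Shank3, a scaffold of the postsynaptic density, and Clstn3 were 1.91-fold and 1.90-fold lower. Phf14, Slco1a5, Cd93, Ggps1 and Vwa8 were 1.89-fold to 1.78-fold lower; the other probe sets of Phf14 and Vwa8 went the same way and that of Ggps1 did not. With no floor 1010 genes passed 2-fold, with the mean of all probe sets 13, and with the higher floor 0. The bacterial control transcripts added before hybridisation differed by −0.28 in median and those added to the RNA before labelling by −0.85. The latter had medians of 7.39 on the TBI array and 6.55 on the hand acupuncture array, below the floor of 7.44, where differences vary most.

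In hand acupuncture against sham, cerebellum markers were lower and neuropeptide genes higher, as on the TBI array; both comparisons subtract the same sham array, so a deviation of that array alone would appear in both. Of 17 cerebellum markers 14 were lower, 6 at least 1.5-fold, with a median log2 difference of −0.57 (percentile 0.0): Fat2 differed by −1.11, Slc1a6 by −0.81, Pcp2, a gene of Purkinje cells, by −0.76 and Ppp1r17 by −0.70. Of 23 neuropeptide genes 21 were higher, with a median of 0.29, led by Calca at 0.40, Pnoc at 0.38, and Grp and Nts, the neurotensin gene, each at 0.37. Oxt, the highest of the list for TBI minus sham, was lower here, at −0.18, and differed by −0.76 for hand acupuncture minus TBI. Forebrain markers had a median of 0.25, with Dlx1 at 0.54 and Drd1, a dopamine receptor gene, at 0.53; with the mean of all probe sets the median was 0.08, within the range of random lists, with no floor it was 0.38, and Adora2a turned from 0.67 to −0.41. Glucocorticoid-responsive genes had a median of 0.12 (percentile 99.80), with Cebpd 0.85 higher.

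Of the other lists, hypoxia and glycolysis genes had a median of 0.10, with Pfkfb4 0.78 higher and Pgk1 0.59 higher (its other probe set went the opposite way), and astrocyte markers of −0.06, with Gjb6 at −0.23. Pericyte and smooth muscle markers had a median of −0.20, with Tagln at −0.87, neuron markers of 0.07 and ribosomal protein genes of −0.01; each of these 3 lists and the hypoxia list lay within the range of random lists with the mean of all probe sets. With no floor the neuron and pericyte medians also lay within it, as did the neuron median under quantile normalization (0.04) and with an offset of 50 before the log, and the higher floor left too few pericyte markers for a percentile. The ribosomal median was −0.03 under quantile normalization. Of further probe sets, 2 of 2 for cerebellum, 2 of 2 for neuropeptide, 3 of 5 for forebrain, 2 of 4 for glucocorticoid-responsive, 3 of 4 for hypoxia, 5 of 10 for astrocyte, 0 of 1 for pericyte, 3 of 9 for neuron and 3 of 5 for ribosomal genes went the way of the probe set used. Immediate early genes had a median of 0.05, with Fosb at 0.74, Egr4 at 0.73 and Egr2 at 0.63, and lay within the central 95% of random lists. At least 2-fold apart were 9 genes higher and 9 lower on the hand acupuncture array, and at 1.5-fold 92 and 83. Gngt2, a G protein gamma subunit, was 2.53-fold higher, Ric3 2.36-fold, Lrrc4 2.24-fold, Utp11 2.21-fold and Palmd 2.14-fold. Phf14 was 3.10-fold lower, with its 3 probe sets in the same direction, Plk5 2.52-fold, Ppfia1 2.18-fold, Fat2 2.16-fold and Zfp111 2.11-fold; the other probe set of Ppfia1 went the opposite way. The number past 2-fold was 1036 with no floor and 1 with the higher floor.

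**Figure D2:**
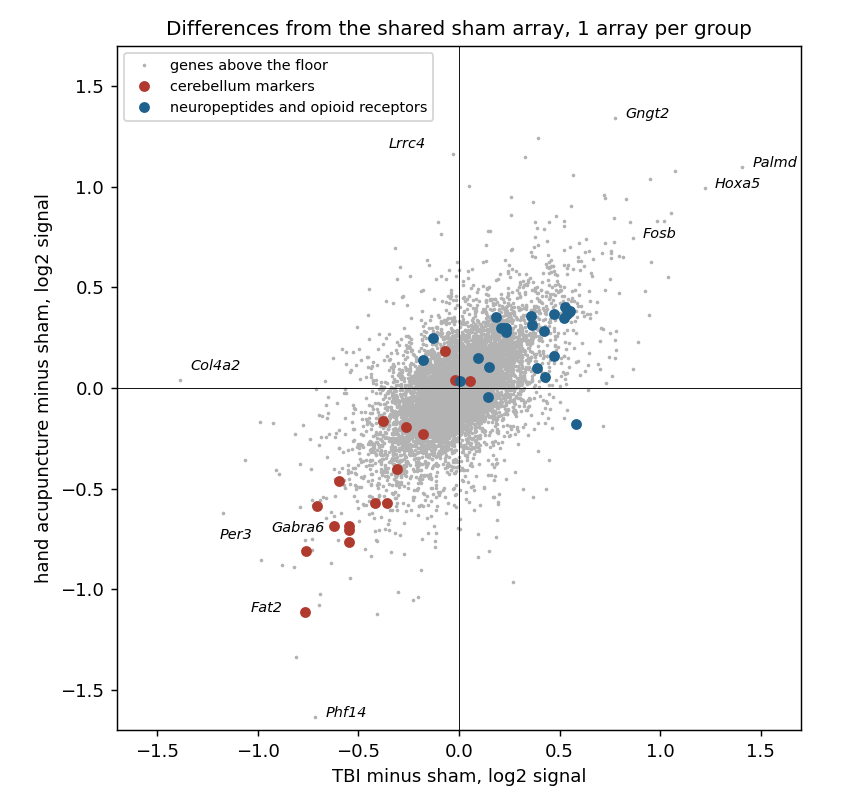
Log2 difference of TBI minus sham (x axis) against hand acupuncture minus sham (y axis) for the 9241 genes above the floor, with 1 array per group; cerebellum markers are red and neuropeptide and opioid receptor genes blue. Both axes share the sham array, which by itself tilts the cloud upward (r = 0.50 with shuffled values, 0.60 observed).

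Whether the hand acupuncture array lay nearer to sham than the TBI array did was read from genes with 1 array apart from the other 2. At 2-fold there were 4 such genes: Palmd and Ttll11 were lower on the sham array than on both others, Col4a2 was lower on the TBI array, and Lrrc4 was higher on the hand acupuncture array. At 1.5-fold, a threshold chosen after seeing that so few passed, the sham array was apart in 54 of 108 genes, the hand acupuncture array in 35 and the TBI array in 19, where arrays that are alike would each hold 33.3%. Next in size were Hoxa5, Pde6g and Klhl42 for sham, Tnfrsf11b, Shox2, Plaa and Cd93 for TBI, and Fbxo41, Cenpx, Phf14 and Ric3 for hand acupuncture. Over genes, TBI minus sham and hand acupuncture minus TBI correlated at r = −0.41. Because the TBI array enters both, shuffling each gene's values among the arrays gave −0.50. The covariance of the differences from the shared array was 0.0157 for TBI, 0.0188 for hand acupuncture and 0.0257 for sham, beside 0.0202, 0.0201 and 0.0201 with shuffled values. The negative relation was thus no stronger than a shared array gives. Without a floor the shares at 1.5-fold were 35.8% for sham, 30.9% for TBI and 33.3% for hand acupuncture, and r was −0.505. With the higher floor the sham array was apart in 14 of 25 genes, the TBI array in 7 and the hand acupuncture array in 4, so the order of TBI and hand acupuncture turned.

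Genes of inflammatory mediators lay mostly below the floor, where signals are near background, and their values are given with that limit. Without the floor, 24 of 36 were higher on the TBI array than on the sham array, 10 of them at least 1.5-fold, with a median of 0.21 (percentile 98.66), and on the hand acupuncture array 26 were higher, with a median of 0.28 (percentile 98.16). Low signals as a whole were higher on the hand acupuncture array: the random lists of like signal had a median of 0.08 in that comparison and 0.03 for TBI minus sham. The chemokine gene Cxcl1 had a log2 signal of 2.64 on the sham array, 6.10 on the TBI array and 5.94 on the hand acupuncture array. Tnf, the gene of tumour necrosis factor, had −0.17, 5.06 and 4.34, Il1b, the gene of interleukin-1 beta, 5.40, 6.68 and 6.30, and Ccl4 5.50, 6.79 and 6.80. Among genes of like signal the SD of TBI minus sham was 1.68 for Tnf, 0.84 for Cxcl1, and 0.43 for Il1b and Ccl4. Ccl20 went the other way, at 4.58, 3.01 and 2.87. Hox genes, which mark the caudal hindbrain and spinal cord, had 3 of 17 members above the floor. Without it, 14 were higher on the TBI array and 14 on the hand acupuncture array than on the sham array, with medians of 0.50 and 0.73 (percentiles 99.79 and 99.93), where random lists of like signal had 0.03 and 0.10. Hoxc5 had log2 signals of 5.31, 6.69 and 6.64, and Hoxb6 of 6.14, 6.82 and 6.92. These genes were chosen after their values were seen.

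**Figure D3:**
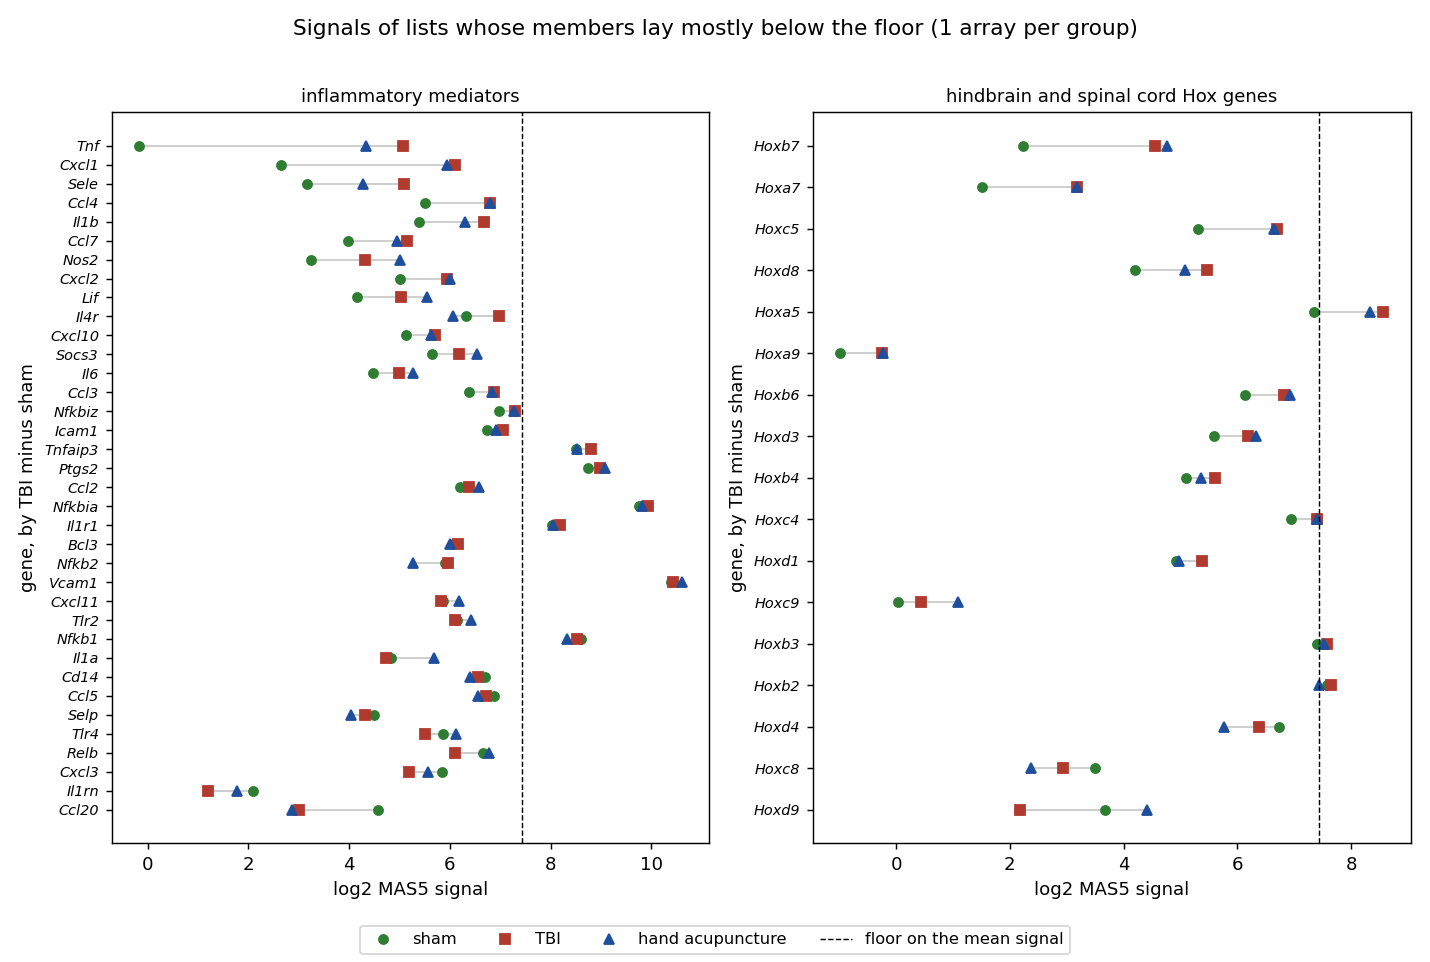
Log2 signal (x axis) of each inflammatory mediator and Hox gene (y axis, ordered by TBI minus sham) on the sham, TBI and hand acupuncture arrays, 1 array per group; the dashed line is the floor of 7.44 on a gene's mean. Cxcl1 lies at 2.64 on the sham array and at 6.10 and 5.94 on the others, and most genes lie left of the line, where differences vary most.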

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

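No paired analysis was possible because each group is 1 array of pooled RNA, and for the same reason no replicate could be left out. Counts at 2-fold (TBI minus sham, hand acupuncture minus TBI, hand acupuncture minus sham) were within 1.5 times of 9, 4 and 18 under quantile normalization and median centring. They were 0, 0 and 1 with the higher floor, 1034, 1010 and 1036 with no floor, and 4, 2 and 7 with an offset of 50. They were 30, 17 and 37 in probe sets, 0, 0 and 0 where all of 2 or more probe sets had to pass, 143, 112 and 175 at 1.5-fold and 0, 0 and 1 at 3-fold. With the mean of all probe sets they were 12, 13 and 18, so the order of the first 2 comparisons turned. Fewer genes enter under the higher floor and noisier ones with none, by construction; the cause of the other shifts was not tested. Genes with 1 array apart from the other 2 numbered 0 with the higher floor, 1388 with no floor and 108 at 1.5-fold, a threshold chosen after seeing the data. The correlation of TBI minus sham with hand acupuncture minus TBI moved from −0.41 to −0.505 with no floor. With no replicates, a list's median was called moved when it shifted by more than 1 SD of its random lists, a gene when it shifted by more than the SD of genes of like signal, and a correlation when it shifted by more than 0.05. The SD limits and this bound were set without any replicate to check them. The cerebellum median for TBI minus sham kept its sign and stood apart under all 6 alternatives; it was −0.4793 with the higher floor, −0.3664 with no floor and −0.4810 with the mean of all probe sets, and reached −0.4793 with 1 member left out. For hand acupuncture minus sham it was −0.4324 with no floor and −0.5155 at the highest with 1 member left out. The neuropeptide median for TBI minus sham also stood apart under all 6; it was 0.2340 with the higher floor, 0.2354 with no floor and 0.2970 at the lowest with 1 member left out. For hand acupuncture minus TBI it was 0.0459 with the higher floor and −0.1328 with the mean of all probe sets. Glucocorticoid-responsive genes stood apart under all 6 in all 3 comparisons, from 0.17 to 0.21, from −0.13 to −0.12 and from 0.09 to 0.13. Among lists that stood apart and named genes at least 1.5-fold apart, signs turned for hypoxia and glycolysis genes, hand acupuncture minus TBI (−0.0006 with the higher floor and −0.0006 with the mean of all probe sets). With that mean they also turned for clock genes, hand acupuncture minus TBI (−0.0344), pituitary and skeletal muscle markers, TBI minus sham (0.2678) and hand acupuncture minus TBI (−0.0514), and ribosomal protein genes, hand acupuncture minus sham (0.0006). The pituitary and muscle list was also 0.0837 for TBI minus sham with 1 member left out and −0.0896 for hand acupuncture minus TBI with the higher floor. Of named genes, Pfkfb4 (−0.1698) and Myh1 (−0.0514) turned for hand acupuncture minus TBI and Adora2a (−0.4063) for hand acupuncture minus sham, all with the mean of all probe sets. The cause of these turns was not tested. Of the 96 list medians, the higher floor moved 23 past that limit and turned 2 that stood apart, the mean of all probe sets moved 20 and turned 5 such, no floor moved 19, quantile normalization moved 12, and median centring and the offset moved 0. Of 331 values of named genes, the mean of all probe sets moved 63 and turned the 3 above, the offset and quantile normalization moved 1 each and median centring 0.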

Other observations

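Several transcripts of excitatory neurons differed on the TBI array from both other arrays. Camk2a, the alpha subunit of calcium/calmodulin-dependent kinase II, was −0.77 from sham and 0.59 higher on the hand acupuncture array than on the TBI array, with 1 of its 2 other probe sets the opposite way in each. Slc17a7, the vesicular glutamate transporter VGLUT1, was −0.74 and then 0.49, and Neurod2, a transcription factor of forebrain neurons, −0.56 and then 0.41. The glutamatergic list as a whole had medians of 0.01 and 0.04, with 12 of 23 members higher in each of these comparisons. These genes were chosen after their values were seen, and differences that share the TBI array are opposite in sign for many genes by construction.

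Of 16 clock genes, 5 were higher and 11 lower on the TBI array than on the sham array, 1 and 3 of them at least 1.5-fold, and the list's median of −0.05 lay within the central 95% of random lists (percentile 15.18). Of members chosen after their values were seen, Per3 differed by −1.17, Dbp by −0.66, Per2 by −0.62 and Nr1d2 by −0.44, while Nfil3 was 0.89 higher and Bmal1 0.12 higher. Of the further probe sets of clock genes above the floor, 4 of 5 went the way of the probe set used. On the hand acupuncture array Per2 differed from sham by −0.40, Per3 by −0.62 and Dbp by −0.08. Among genes of interferon response, Rsad2 was 0.78 higher on the TBI array than on the sham array and Irf7 differed by −0.45, and of antioxidant genes Hmox1, haem oxygenase 1, differed by −0.51 between hand acupuncture and TBI.

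In the weighing that follows, the tests of granule and Purkinje cells, of neuropeptide subsets and of the glucocorticoid list on the hand acupuncture array were chosen after the results were seen; the second cerebellar set and the second glucocorticoid set were written before their values were looked at. Cerebellum markers were lower on the TBI and hand acupuncture arrays than on the sham array. A second set of cerebellar genes, 10 of them above the floor and in none of the first lists, had medians of −0.24 and −0.25 against sham, and the higher of its 2 percentiles among random lists was 0.020. The 17 cerebellum markers split into 9 granule cell genes, with a median of −0.54 for TBI minus sham, and 8 Purkinje cell genes, with −0.31; the higher of their percentiles was 0.000, which argues against a change in 1 of these cell types alone but, as these are the same genes, adds no evidence for the pattern. Candidate explanations that stay open are more cerebellum with the brainstem in the sham pool, where the dissection is not described in the labels, and an effect of injury on cerebellar transcripts, which was not tested; the second set would be low under either.

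Neuropeptide genes were higher on the TBI and hand acupuncture arrays than on the sham array. Without the members made mainly in the hypothalamus (Pmch, Hcrt, Avp, Oxt, Crh, Trh and Pomc) the medians were 0.23 and 0.30 and the lower percentile was 100. Whether the members kept are also made in the hypothalamus was not checked, so this cannot decide whether more hypothalamic tissue was the cause. Of the members left out, Pmch was 0.36 higher than sham on both arrays. Oxt was 0.58 higher on the TBI array and differed by −0.18 on the hand acupuncture array. A lower cerebellar share could raise all other neurons alike: for TBI minus sham the neuropeptide median exceeded that of 10 neuron identity genes taken from the monoaminergic and cholinergic lists without receptors by 0.150, within 2 SD of the difference between random lists (0.163), and that of the cholinergic list by 0.150, within 2 SD (0.230). Both of these medians were 0.2092 and came from the same cholinergic genes, so the 2 gaps are not separate evidence. The neuropeptide median exceeded that of the whole monoaminergic list by 0.236, beyond 2 SD (0.133), but by 0.130 with the higher floor and 0.120 with no floor, within 2 SD (0.160 and 0.145). Under a lower cerebellar share, the neuropeptide median was to lie within 1 SD of each of these medians. It did not: 1 SD was 0.0815 for the identity genes, 0.1151 for the cholinergic and 0.0666 for the monoaminergic list. Nor did it exceed each of them by more than 2 SD, the condition set against that explanation. A lower cerebellar share and a treatment effect on peptide genes cannot be told apart here. The gap depends on the genes compared and on the floor, and there is 1 pool per group.

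Glucocorticoid-responsive genes were higher on the TBI array than on the other arrays. For hand acupuncture minus sham the list lay at percentile 99.800, a value known when the list was chosen, where a deviation of the TBI array alone would leave it in the central range. The second set had a median of −0.04 there (percentile 14.04). It did not stand apart for TBI minus sham either, so it cannot decide this. With 1 pool per array and a list chosen with its value known, a deviation of the TBI array alone stays open. A higher level of glucocorticoid-responsive transcripts at large was tested with the second set, which was to lie above the central 95% of random lists for TBI minus sham; it did not, with a percentile of 90.470. By the rule written before its values were looked at, this counted against that explanation. The second set's median, 0.0595, fell short of the upper end of that range, 0.0860, by less than 1 SD of the random medians (0.0403). A tolerance of that size was added only after the value was seen, so it cannot turn the outcome. Stress of handling and injury may each act on these genes, and 1 pool per group cannot separate them.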
